A study of Caenorhabditis elegans with 2 samples.

How the data were processed

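Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map CEH-58, a homeodomain protein of the nematode Caenorhabditis elegans, in whole young adult worms at 65 hours. Per the labels, the worms carried an integrated fosmid transgene in which ceh-58 was fused to an enhanced GFP tag, and the fusion was precipitated with an anti-GFP antibody from chromatin sonicated to 200 to 800 bp. There were 2 biological replicates in 1 group and no second condition, so the comparisons lay between the replicates, and between the peaks and the rest of the genome. Control alignments entered the authors' processing, and their data were not analysed here. Read counts per library were not used here, so the depth behind a peak is unknown.

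The authors deposited 4 thresholded peak lists and 4 longer lists of candidate peaks on assembly ce11, per the labels. A conservative list held peaks reproducible between the biological replicates, an optimal list was the looser call on pooled reads, and each replicate had a list of its own. All conservative peaks were also in the candidate list that compared the replicates. The aligner, the peak caller and their versions are not given in the sources used here. The authors ranked candidates by the irreproducible discovery rate (IDR), the expected share of irreproducible peaks at a rank, and deposited an IDR score that is a scaled log of that rate with a maximum of 1000. All thresholded lists began at an IDR of 0.01, per the values in the files. The authors also deposited a signal value per peak, in a column without a header, and this is the authors' own value. It was used to rank peaks and to compare RNA gene classes within a list, and for the correlation and ratio between the replicates. They deposited a −log10 q-value per peak as well, which entered no test. Signals of the 2 replicates come from separate libraries of unknown depth and are given without scaling. The 2 replicate signal columns of the candidate list do not name their replicates and entered only measures that treat both alike. Signals given by replicate come from each replicate's own candidate list, as the highest signal among candidates that overlap the peak by at least 1 bp.

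Peak positions were compared with the same assembly in the reference (WBcel235), whose 6 nuclear chromosomes contained all peaks, and with Ensembl release 115 gene models. There were 19973 protein-coding genes with 29784 distinct transcript starts. A promoter window ran from 1000 bp upstream to 200 bp downstream of such a start. RNA genes and pseudogenes counted as near a summit at up to 200 bp. Random placements put each summit at a uniform position of its own chromosome 100000 times, and the tests were one-sided unless named as two-sided. Where gene lists were tested by random placement, 10000 placements were made and the tests were two-sided. Overlap between replicate lists required at least 1 bp and was tested with 100000 placements in the same way. Gene lists, 20 in all, were tested with two-sided Fisher's exact tests against all protein-coding genes. Words of 6 bases (6-mers) within 50 bp of the summit were compared with flanks 200 to 250 bp to either side by a two-sided exact sign test. Chromosome counts were compared with the share of length by two-sided exact binomial tests. Adjusted p-values are Benjamini-Hochberg values within each family. Intervals are exact Clopper-Pearson 95% intervals unless named as odds ratio intervals, and they cover counting error only. The limit given for a count of 0 in a gene list is instead 3 counts of the total. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

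The tests, the gene lists, 12 sequence motifs and the rule for named genes were fixed before the data were examined. The rule takes genes with a promoter summit among the 20 conservative peaks of highest signal, or else the nearest start. It adds ceh-58, the 4 members with the highest signal of each list past the threshold, the top member of other lists with at least 3 members at a summit, and the 5 6-mers with the smallest p in each direction. Other genes named below were chosen after their values were seen. The class of pseudogenes, the division of the remaining ncRNA genes by annotated type, the comparison of signal between RNA gene classes, the GC content of summits and the measure of unique sequence were also added after the data were seen. Alternatives were other peak sets, promoter windows, overlap rules, backgrounds and 6-mer windows, and the use of each replicate's own list in place of both. Alternatives added after the data were seen were the peaks at the highest IDR score, the peaks away from RNA genes, the candidates missing from the conservative list put back, other distances to RNA genes, ncRNA genes away from the other RNA classes, the set without the 20 highest peaks, the other lists at ceh-58, and random positions of equal GC content. For summits near RNA genes and for exon, intron and outside-gene shares, the optimal and single-replicate lists were also added then, as was the background of candidates that were not reproducible for summits near RNA genes. Sequence was called unique where at least 90% of the 31-mers in the 200 bp around a summit occurred once in the genome. The procedures were tested on simulated peak sets of 483 summits. With 40 summits moved to transcript starts, 45 of 50 sets passed the promoter test, against 1 of 50 unmodified sets. With 5 ribosomal protein starts planted, that list passed in 50 of 50 sets of 19973 genes, and no list passed in any unmodified set. A 6-mer planted at 40 summits passed in 5 of 5 sets, and 0 6-mers passed in the unmodified ones. The simulated summits lay at random positions, without the higher GC content of the real summits. The simulation thus does not show how the 6-mer test behaves under that difference.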

Results

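The series asks where a GFP fusion of CEH-58, a homeodomain transcription factor, is found in the genome of young adult worms. Anti-GFP ChIP-seq was available from 2 biological replicates of whole animals of 1 transgenic strain. The conservative list, which holds peaks reproducible between the replicates, contained 483 peaks and was used as the main peak set. The optimal list from pooled reads contained 732 peaks, and the replicates' own lists contained 156 and 92 peaks for replicates 1 and 2. Not all conservative peaks were in the optimal list, which overlapped 406 of the 483 (84.1%). Of the conservative peaks, 98.6% had the same width of 236 bp, and the median signal was 72.4. Coordinates are those of ce11.

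The highest conservative peaks lay at genes of small non-coding RNAs and in stretches of repeated sequence. The top peak (V, 12303561 to 12303703, signal 305.7) lay in an intron of frm-7, within 200 bp of the snoRNA genes C51F7.3 and C51F7.4, and had signals of 178.8 and 120.7 in replicates 1 and 2. Its nearest protein-coding start, that of F55C5.17, was 1097 bp away. Second came a peak in an intron of pxn-1, which encodes a peroxidasin, at the snoRNA gene ZK994.7 (V, 8500514 to 8500642, signal 283.8), with replicate signals of 139.7 and 138.8. An intron of ints-8, an Integrator complex subunit, held a peak at rpr-1, the gene of the RNase P RNA (I, 13463872 to 13463983, signal 217.1, replicates 130.2 and 85.3). Peaks at snoRNA genes also lay in an intron of cutl-18 (signal 170.1), near W03C9.1 (167.9) and 620 bp upstream of the chemoreceptor gene sre-23 (164.8). In all, 6 of the 20 highest peaks lay within 200 bp of an RNA gene, 5 of them at snoRNA genes, and 3 of the 20 lay in a promoter window. These 3 belonged to sre-23, to the ribosomal protein gene rpl-3, whose summit was 275 bp upstream of the start (III, 3867461 to 3867696, signal 146.1, replicates 92.8 and 52.2), and to the divergent Hsp70-family genes F44E5.4 and F44E5.5 (II, 11759342 to 11759577, signal 143.9, replicates 84.1 and 61.9).

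The other peaks of the top 20 lay outside the promoter windows. An intronic peak in tir-1, the worm SARM1 gene, had a signal of 220.3, and an intronic peak in the calcium/calmodulin-dependent kinase gene cmk-1, nearest to the start of ccm-2, had 207.9. A summit 1080 bp upstream of eif-3.G, a translation initiation factor subunit, lay in an intron of lips-10 and had 149.8. Peaks outside protein-coding genes were nearest to VY10G11R.1 (224.7), Y53G8AR.1 (210.1), Y54F10AM.8 (2 peaks, 193.5 and 193.4), Y102A11A.1 (168.5), pqn-21 (163.5), T02H6.11 (149.0), the F-box gene fbxa-190 (145.9) and the zinc finger gene fezf-1 (143.2). Sequence around 11 of the 20 highest summits was not unique, with at most 31.8% of its 31-mers found once in the genome, and among the 14 summits away from RNA genes 3 lay in unique sequence. For the 11, which copy of the sequence the reads came from is uncertain, and so is the gene named.

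Summits were concentrated at genes of tRNAs, snoRNAs and snRNAs. Within 200 bp of a tRNA gene lay 55 of 483 summits (11.4%, interval 8.69 to 14.6), against a mean of 1.27 in random placements, a 43.2-fold excess. Genes of snoRNAs, which guide RNA modification, had 28 summits against 0.904 (31.0-fold), and snRNA genes had 10 against 0.323 (31.0-fold). Other annotated ncRNA genes had 71 against 16.4 (4.34-fold), but 48 of the 71 also lay near a gene of the other 3 classes. The permutation p of each of these 4 classes was 1e-05, the smallest the placements can give, with an adjusted p of 3.5e-05 over 14 annotation classes in the same permutation test. The 23 remaining ncRNA summits, against 15.4, did not pass (permutation p = 0.0384, adjusted p = 0.0768). Together 93 summits (19.3%) lay near a tRNA, snoRNA or snRNA gene, against 2.49 in random placements. In the replicates' own lists these were 32 of 156 summits (20.5%) and 16 of 92 (17.4%), each again at the smallest permutation p of 1e-05. The 93 summits marked 64 of 612 tRNA genes, 29 of 346 snoRNA genes and 10 of 129 snRNA genes. The snRNA genes included sls-2.1, sls-2.2, sls-2.4 and sls-2.14, which encode the SL2 spliced leader. No summit lay near an rRNA gene, against a mean of 0.0894 in random placements.

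**Figure D1:**
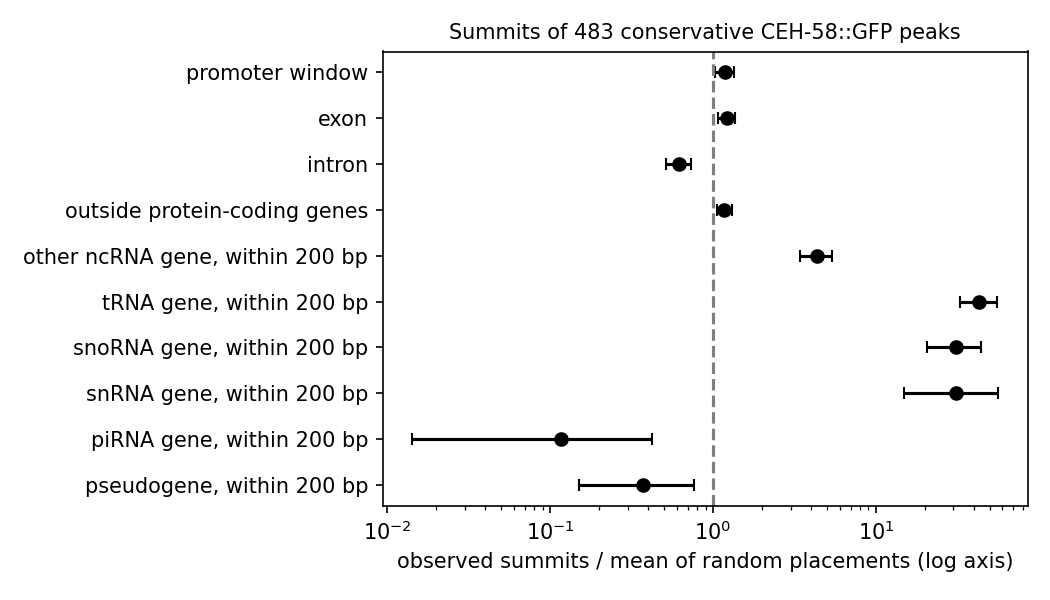
Ratio of observed summits to the mean of random placements (log axis) for the 483 conservative peaks, by annotation. Points are ratios, bars are 95% Clopper-Pearson intervals of the observed share, and the dashed line marks a ratio of 1; tRNA, snoRNA and snRNA genes lie at 43.2, 31.0 and 31.0.

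Within the conservative list, peaks at snoRNA genes were also higher than the rest. Their median signal was 95.04 (n = 28), against 71.3 for other peaks (n = 455, two-sided permutation p = 1e-05, the smallest the permutations can give, adjusted p = 4e-05 over 4 classes). At tRNA genes the median was 73.5 (n = 55), against 71.8 elsewhere (n = 428, permutation p = 0.382). Peaks at other ncRNA genes, 48 of them also near the other classes, had 78.1 (n = 71) against 71.1 (n = 412, permutation adjusted p = 0.0255), and peaks at snRNA genes 65.5 (n = 10) against 72.5 (n = 473, permutation adjusted p = 0.109). The highest peak at a tRNA gene had a signal of 120.4 and lay at an alanine tRNA gene on X (summit 6292337). Sequence was unique at 28 of 28 snoRNA summits, 3 of 10 snRNA summits and 4 of 55 tRNA summits. At tRNA summits the median share of 31-mers found once was 68.2%, so sequence that missed the rule was often partly unique. The rule can fail where only the gene's own sequence is repeated. Single tRNA genes stay uncertain.

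Listed summits were found in promoter windows slightly more often than random positions were. There were 150 such summits (31.1%, interval 26.95 to 35.4), against 126.2 in random placements (1.19-fold, permutation p = 0.00832, adjusted p = 0.0166). It did not pass in the replicates' own lists, with 46 of 156 summits in replicate 1 (29.5%, above the random mean of 41.1, permutation p = 0.212) and 20 of 92 in replicate 2 (21.7%, below the random mean of 24.4, permutation p = 0.877). Nor did it pass among the 244 peaks with the highest IDR score (27.05%, random mean 63.7, permutation p = 0.394). With 173 reproducible candidates that the list lacks put back, the share was 23.9%, under the random mean (permutation p = 0.910). Only 7 of these 173 lay in promoter windows, so adding them had to lower the share. Of the 173, 88.4% lay in sequence that the reference soft-masks. The random positions covered whole chromosomes, including soft-masked sequence, which made up 35.7% of the genome but held 20.9% of listed summits. Whether sequence that the list lacks accounts for the promoter excess was not tested. The same limit holds for the pseudogene and outside-gene counts below. Introns held 100 summits (20.7%), fewer than the random mean of 162.4 (permutation p = 1e-05, the smallest the placements can give), but positions of equal GC content gave 116.4, and the two-sided permutation p was then 0.0826. Fewer summits also lay near piRNA genes (2 against 17.1) and pseudogenes (7 against 18.8), with permutation adjusted p-values of 7e-05 and 0.00658. Positions of equal GC content were not drawn for these classes, so GC content stays open for both. Exons held 174 summits (36.0%) against 142.8 at random positions (permutation p = 0.00137), but random positions of equal GC content gave 216.2, so the direction turned. Protein-coding gene bodies did not contain the remaining 209 summits (43.3%), against 177.8 at random positions (permutation p = 0.00182); away from RNA genes the share was 38.7% (two-sided permutation p = 0.360).

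The promoter summits marked 160 protein-coding genes, or 0.801% of all, and 2 of 20 gene lists passed the threshold. Cytosolic ribosomal protein genes had a promoter summit at 5 of 82 members, against 0.657 by chance (odds ratio 8.27, interval 2.57 to 20.5, Fisher's exact test adjusted p = 0.0103). They were rpl-3 (signal 146.1), rps-24 (101.0), rla-1 (100.1), rpl-15 (97.1) and rps-16 (87.5). Each had a candidate in both replicates, as did 476 of all 483 conservative peaks. The peaks at rpl-3 and rla-1 overlapped a peak in both replicates' own lists. That at rps-24 overlapped one in replicate 1's list only, and those at rpl-15 and rps-16 in neither. Sequence was unique at 4 of the 5, and at rps-24 60% of 31-mers were found once. At rla-1, a ribosomal stalk protein gene, the replicate signals were 50.6 and 56.7, and at rps-24 they were 68.3 and 31.9. Counted anew from each replicate's own summits, the list passed with replicate 1's peaks at 4 members (Fisher's exact adjusted p = 0.00133). It missed the threshold with replicate 2's at 2 members (Fisher's exact adjusted p = 0.0867).

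Histone genes had a promoter summit at 4 of 72 members, against 0.577 by chance (odds ratio 7.45, interval 1.95 to 20.3, Fisher's exact adjusted p = 0.0267). The members were his-63 (signal 83.5, replicates 54.7 and 24.7), his-68 (69.9, 42.9 and 32.5), his-60 (66.6, 31.5 and 35.6) and his-59 (62.8, 32.8 and 32.2). The summits assigned to his-68 and his-59 lay inside exons of the neighbouring genes his-67 and his-60, and sequence was not unique at his-63 (74.1%) and his-59 (77.1%). The call did not hold in the optimal list (Fisher's exact adjusted p = 0.0532), with random placement of the summits (permutation adjusted p = 0.126), or with the narrower window, where 1 member remained (Fisher's exact adjusted p = 0.708). Replicate 1's own peaks gave 2 members (Fisher's exact adjusted p = 0.157) and replicate 2's gave 0. The call held with the wider window, at 7 members (odds ratio 6.72, Fisher's exact adjusted p = 0.00104). It also held at 4 members away from RNA genes (Fisher's exact adjusted p = 0.00989) and with the missing candidates put back (Fisher's exact adjusted p = 0.0299).

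The other 18 lists did not pass. Chemoreceptor genes had 4 of 1364 members at a summit, against 10.9 by chance (odds ratio 0.348, Fisher's exact adjusted p = 0.175), with sre-23 the highest, and passed as fewer than by chance with the wider window (odds ratio 0.213, Fisher's exact adjusted p = 0.000168) and by nearest start (0.347, adjusted p = 0.000731). With the main window, random placement of the summits gave 7.72 chemoreceptor genes against the 4 found (0.518-fold, permutation adjusted p = 0.850). Random placement was not run with the wider window or by nearest start. Oxidative phosphorylation genes had 2 of 41 (cox-6A and cyc-2.1, Fisher's exact adjusted p = 0.213), cuticle collagens 2 of 175 (col-52 and col-142) and innate immune effectors 2 of 306 (clec-206 and spp-26). Sequence at col-52 (5.29% of 31-mers found once) and cox-6A (52.4%) was not unique, so these genes are uncertain. Single members were found among heat shock proteins (hsp-90, signal 79.1) and muscle structural genes (unc-52). The heat shock list holds genes named hsp, so not F44E5.4 and F44E5.5. Detoxification enzymes (cyp-43A1) and translation factors and tRNA synthetases (rars-1) also had a single member each. Sequence was not unique at spp-26 (65.9%) and cyp-43A1 (67.6%). The spp-26 and cyp-43A1 summits lay within 200 bp of a tRNA gene, and the cox-6A summit within 200 bp of an snRNA gene. They are thus also among the summits near RNA genes described above. None of the 98 homeobox genes had a promoter summit, which allows a share of up to 3.06% (3 counts of the total), nor did any F-box and MATH-BTB gene (395 genes) or nuclear hormone receptor gene (274). With the wider window the F-box and MATH-BTB genes, still at 0, passed as fewer than by chance (odds ratio 0, Fisher's exact adjusted p = 0.0175). The further lists with no member at a summit were neuropeptide and insulin-like genes, germline genes, intestine genes, major sperm proteins, neurotransmitter identity genes, pan-neuronal synaptic and secretory genes, and proteasome subunits. The 10 lists without a member together held 1058 genes.

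Sequence at the summits was richer in G and C than that of the flanks. GC content averaged 47.6% ± 9.31 (SD, 483 summits) at summits and 37.0% ± 8.48 in flanks, and it was higher at 397 of the 483 summits. Of 2080 6-mers, 107 were more frequent at summits and 134 less frequent (exact sign tests). GAACCC was found at 42 summits and in 5 flanks (exact sign test adjusted p = 3.49e-07), and 23 of these 42 summits lay near tRNA genes. CTGAGC (35 and 4), CACTCG (33 and 5), CTCTAC (35 and 7) and GCACAC (34 and 6) followed. Of their summits, 23, 8, 19 and 4 in this order lay near tRNA genes. AAAAAT was found at 102 summits and in 216 flanks (exact sign test adjusted p = 3.94e-13), followed by AAAAAA (66 and 171), AAAATA (61 and 160), TAAAAA (51 and 143) and TGAAAA (64 and 160). Against random windows of the same GC content, 0 6-mers passed in either direction by the exact sign test, with an exact adjusted p of 0.139 for GAACCC. AAAATA (50 such windows) and TAAAAA (50) then lay at slightly more summits than windows. The windows came from a single random draw, so only the loss of their deficit can be read from this. Away from RNA genes GAACCC lay at 13 summits and in 3 flanks (exact adjusted p = 0.201).

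Of the 12 motifs fixed before the data were examined, 3 passed over all 6-mers, and all 3 were less frequent at summits. These were the T-block AAAAAA, the GATA factor site TGATAA (8 summits, 47 flanks, exact sign test adjusted p = 6.71e-06) and the homeodomain variant TTAATT (33 and 70, exact adjusted p = 0.00178). Against windows of equal GC content none of the 3 passed, and TTAATT was no longer less frequent, with 33 summits and 26 windows (TGATAA 8 and 25, exact adjusted p = 0.338). TAATTA, a palindrome bound by many homeodomains, lay at 9 summits (1.86%, interval 0.855 to 3.51) and in 25 flanks (exact sign test adjusted p = 0.0543, and 0.021 adjusted over the list alone), and in 8 windows of equal GC content. Adjusted over the list alone, GAGAGA (45 and 25, exact p = 0.0363) and CTGCGT (27 and 12, exact p = 0.0474) passed as more frequent at summits, so 6 of the 12 passed. CAATTA (20 and 29), CACGTG (6 and 4), TTCGCG (13 and 12), TGACTC (12 and 8) and the control palindromes ATCGAT (9 and 14) and GGCGCC (7 and 4) passed neither way.

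The replicates shared more peaks than chance gives, but fewer than their lists held. Of replicate 1's 156 peaks, 50 overlapped a replicate 2 peak (32.1%, interval 24.8 to 39.99), and the same number made up 54.3% of replicate 2's 92 peaks. Random placement gave a mean of 0.0635 (permutation p = 1e-05, the smallest the placements can give). Of the 483 conservative peaks, 49 overlapped a peak in both replicates' own lists and 333 (68.9%) overlapped neither. Across the 483 peaks, which are not independent replicates, the log2 signals of the replicates had a Pearson r of 0.519 and a Spearman rho of 0.231 (permutation p = 1e-05 each, the smallest the permutations can give). These peaks were selected for reproducibility between the same replicates, and over all 105945 candidates r was 0.270 and rho 0.255. For 701 peaks of the optimal list they were 0.353 and 0.138. These came from signals in each replicate's own candidate list, so the measure of signal differs. Without the 20 peaks of highest pooled signal, r was 0.257 and rho 0.129 (permutation p = 1e-05 and 0.00537). Signal was higher in replicate 1 at 350 of 476 peaks with a candidate in both, at a median ratio of 1.22 and an SD of 0.42 on the log2 scale.

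**Figure D2:**
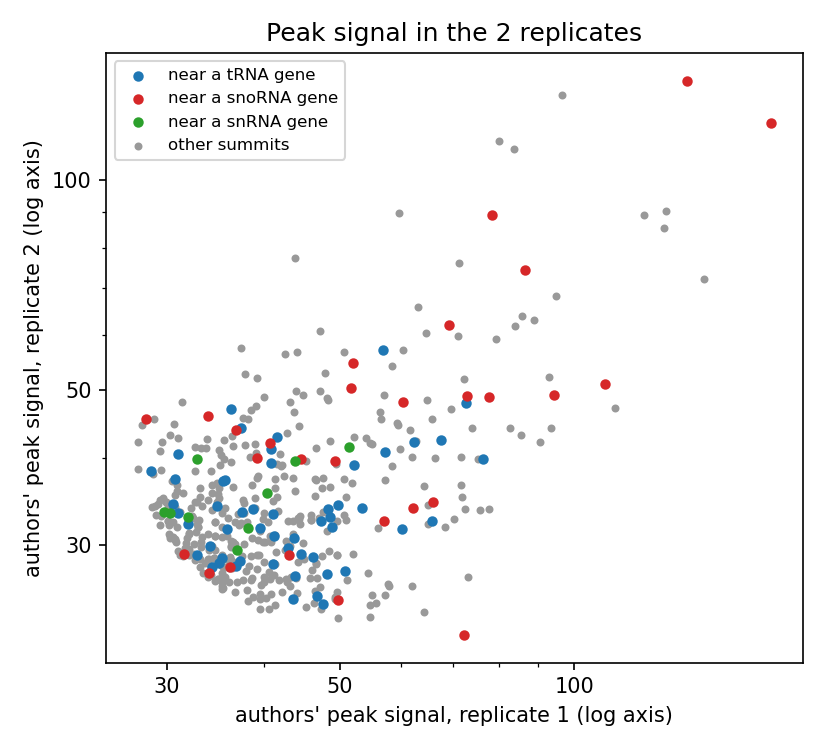
Authors' peak signal in replicate 1 (horizontal log axis) and replicate 2 (vertical log axis) for the 476 conservative peaks with a candidate in both replicates. Each point is a peak, coloured by the class of RNA gene within 200 bp; the peaks at the upper right, 178.8 and 120.7 and 139.7 and 138.8, lie at snoRNA genes.

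No chromosome's share of all peaks passed against its share of length, but 2 did away from RNA genes. Chromosome I held 89 peaks (18.4%, against 15.03% of length, exact binomial p = 0.0414, adjusted p = 0.248), II 65, III 73, IV 91, V 90 and X 75, and 0 of 6 passed the adjusted threshold by the binomial test, 1 of them having an unadjusted p under 0.05. Against the share of protein-coding genes, I was higher (14.4% of genes, exact binomial adjusted p = 0.0413) and V lower (18.6% of peaks, 25.004% of genes, exact binomial adjusted p = 0.00657). Of the 367 peaks not near a tRNA, snoRNA, snRNA or other ncRNA gene, X held 41 (11.2%, against 17.7% of length, exact binomial adjusted p = 0.00458) and I held 75 (20.4%, against 15.03%, exact binomial adjusted p = 0.0161).

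No peak was called at the tagged gene itself, which the worms also carried on the fosmid transgene. ceh-58 occupies II, 10367741 to 10369597 on the minus strand, and 0 peaks of any of the 4 thresholded lists had a summit in it or within 2000 bp. The much longer candidate lists were also empty there. In the list of 105945 candidates between replicates, the nearest summits were at 10355279 and 10390665, a gap of 35386 bp. The gap was 36231 bp in replicate 1's candidates and 37065 bp in replicate 2's, against a median of 627 bp between neighbouring candidates in the list between replicates. The gap contained the whole of C07E3.4, the homeobox gene ceh-57, ceh-58 and the zinc finger gene ztf-27.

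**Figure D3:**
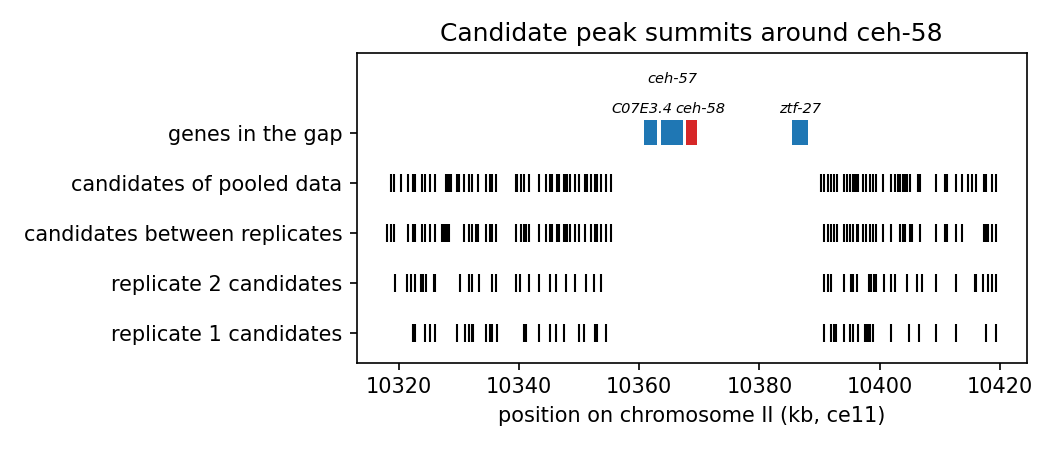
Candidate peak summits (black ticks) along chromosome II (kb, ce11) around ceh-58 in the 4 candidate lists, with the genes inside the gap as bars, ceh-58 in red. All 4 lists lack candidates from about 10355279 to 10390193.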

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

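The tests below were chosen after the missing candidates had been seen, and all but that of unique sequence after the value they measure was seen too. A signal appeared in data outside the thresholded lists. Of 656 candidates with an IDR of at most 0.01 between the replicates, 173 (26.4%) were missing from the conservative list, and they included the strongest of all. The highest had a signal of 3627 (X, 15810955 to 15811191, replicates 1945 and 1860), against at most 305.7 in the list, and 37 of the 173 exceeded every listed peak. Each replicate's own list likewise lacked 121 of 277 candidates at that IDR in replicate 1 and 149 of 241 in replicate 2, and the optimal list lacked 186 of 918.

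These missing candidates lay away from genes. Only 7 of the 173 were in promoter windows, against a mean of 45.2 in random placements, and 159 (91.9%) lay outside protein-coding genes (permutation p = 1e-05 each, the smallest the placements can give). Repeated sequence may account for them. Of their summits 88.4% were in sequence that the reference soft-masks, against 20.9% of listed summits, 25.1% of the other candidates and 35.7% of the genome. Reads shared between near-identical copies may add to this, since 1.73% of the missing candidates lay in unique sequence (interval 0.359 to 4.98), against 66.9% of listed peaks. The thresholded lists derive in addition from a further file whose content is not stated in the sources used here, and no biological explanation was tested.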

How the results depend on the processing

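Alternatives chosen after the data were seen are the peaks at the highest IDR score, the missing candidates put back, the peaks away from RNA genes, other distances to RNA genes, ncRNA genes away from the other RNA classes, the set without the 20 highest peaks, other lists at ceh-58 and equal GC content. For RNA genes and for exon, intron and outside-gene shares they include the optimal and single-replicate lists, and for RNA genes the background of candidates that were not reproducible. An IDR of at most 0.01 removed no peak, so that comparison is void. No paired analysis was possible because there is only 1 group. The excess at tRNA, snoRNA and snRNA genes, the sharing of peaks, the replicate correlation and the absence of peaks at ceh-58 kept their direction and side of the threshold in every alternative run for them. The share near other ncRNA genes was 4.76% away from the other RNA classes, short of the threshold because 48 shared summits were left out. The promoter share was 21.7 to 29.5% with single replicates, 27.05% at the highest IDR score and 23.9%, below chance, with the missing candidates put back. Of the 173 put back, 7 lay in promoter windows, which by itself lowers the share. Genes with a promoter summit numbered 24 to 53 with single replicates, 77 at the highest IDR score, 92 and 321 with the narrower and wider windows, and 437 by nearest start. Lists past the threshold numbered 0 to 1 with single replicates, 1 at the highest IDR score, 1 and 4 with the narrower and wider windows, and 1 with random placement. The odds ratio of ribosomal protein genes was 20.8 to 22.6 with single replicates, short of the threshold with replicate 2's peaks, 17.9 at the highest IDR score and 14.8 with the narrower window. That of histone genes was 0 to 11.1 with single replicates, 4.99 in the optimal list, 3.67 at the highest IDR score, 3.07 with the narrower window and 2.64 by nearest start, and random placement gave 9.66-fold, none past the threshold. Histone genes did pass with the wider window (6.72), away from RNA genes (9.86) and with the missing candidates put back (7.21). The 6-mers more and less frequent at summits numbered 0 to 5 and 2 to 9 with single replicates, and 31 and 70 at the highest IDR score. Away from RNA genes they numbered 19 and 70, and with equal GC content 0 and 0. Those more frequent numbered 289 in the optimal list and 175 against random promoter positions. With equal GC content AAAATA, TAAAAA and TTAATT (AATTAA on the other strand) were at 11, 1 and 7 more summits than control windows. Exon shares turned below chance with single replicates (20.7 to 26.3%), at the highest IDR score (27.05%), with the missing candidates put back (28.2%) and with equal GC content, where 44.8% of random positions were exonic. Chromosomes past the threshold numbered 2 away from RNA genes and 2 against gene shares. Fewer peaks lower the power of the single-replicate and stricter sets, and apart from that and from GC content the cause was not tested.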

Other observations

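The tests below were chosen after the patterns they concern were seen, except the optimal list and the nearest start as alternatives for gene lists. Those of GC content at RNA genes, of unique sequence over all 93 summits, of how many genes lie in gaps and of unique sequence in the gap had their bounds written before their own values were seen, and the others after. Of the 612 tRNA genes, 276 lie on X, and 35 of these had a summit (12.7%), against 29 of 336 on the autosomes (8.63%, odds ratio 1.54, interval 0.884 to 2.69, Fisher's exact p = 0.112). Cysteine tRNA genes had a summit at 6 of 13 members, on 5 distinct summits (46.2%, Fisher's exact adjusted p = 0.0219 over 22 classes), and alanine tRNA genes at 8 of 34 (Fisher's exact adjusted p = 0.202). Sequence at most tRNA summits missed the rule for unique sequence, with a median of 68.2% of 31-mers found once. These counts by class carry that uncertainty.

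When each summit was given to its nearest protein-coding start, which marks 437 genes, 14 of 82 ribosomal protein genes were among them (odds ratio 9.48, against 8.27 with promoter windows, Fisher's exact adjusted p = 5.31e-08), including rps-3, rps-6, rpl-7A and rpl-21. By the same rule 10 of 175 cuticle collagens were nearest to a summit, dpy-13 among them (odds ratio 2.75, Fisher's exact adjusted p = 0.0353), which did not pass with the promoter window. In the optimal list, heat shock proteins, a list of genes named hsp that leaves out F44E5.4 and F44E5.5, passed with 3 of 22 members (odds ratio 13.4, Fisher's exact adjusted p = 0.0212). These were hsp-90 and the endoplasmic reticulum Hsp70 genes hsp-3 and hsp-4, with signals of 79.1, 53.7 and 58.7.

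The first pattern to weigh is the excess of summits at tRNA, snoRNA and snRNA genes. GC content does not account for it, since random positions of equal GC content lay near these genes 5.14 times on average, against 93 summits. TAATTA was absent within 50 bp of these summits, at 0 of the 93 (0%, interval up to 3.89). Since 9 of all 483 summits had it, a low share was set before the 93 were counted. The count therefore shows only that this word is not at the 93 summits, and binding through other sequence was not tested. Reads shared between near-identical gene copies stay open for the 93 summits as a whole. Of these, 37.6% lay in unique sequence (interval 27.8 to 48.3). A split by class, chosen after that value was seen, gave 100% of 28 for snoRNA genes, which argues against shared reads there. It gave 30% of 10 summits for snRNA genes, too few to decide. For tRNA genes it gave 7.27%, but a median of 68.2% of 31-mers at these summits occurred once. The rule can fail where only the gene's own sequence is repeated, so the 7.27% cannot decide for tRNA genes. Recovery of highly transcribed loci in any immunoprecipitation was not tested and stays open, as neither transcription nor an untagged or unrelated immunoprecipitation was analysed here. Apart from the count of TAATTA, no biological explanation was examined.

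The second pattern is the gap without candidates around ceh-58. A stretch that lacks candidates by its ordinary nature is argued against, as 1.24% of protein-coding genes (248 of 19973) lie in a gap at least as long. Such gaps are rare but also occur elsewhere. Of 105951 gaps between candidates, 49 were at least as long, and the longest was 152019 bp. Sequence in which reads cannot be placed is argued against too, since 91.5% of the 31-mers in the gap occur once in the genome. What lies behind the gap stays open, since read coverage was not analysed here and the strain of the control is not given in the sources used here. The worms also carried ceh-58 on the integrated fosmid transgene, and its part in the gap was not tested. Missing candidates in the gap therefore cannot be read as missing binding. No biological explanation was tested.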
